A study of Mus musculus with 4 samples.

How the data were processed

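Total RNA of 2 samples of B220+ splenocytes and 2 B-cell lymphoma lines was hybridised, as Cy3-labelled cRNA, to mouse oligonucleotide arrays with 43379 non-control spots each. Images were extracted with Agilent Feature Extraction, version 9.5.1.1 per the file headers and 9.5 per the submitters' notes, and the array annotation uses the mm8 build. The deposited processed signal of each array is an intensity, corrected for background and for spatial trends within the array, with surrogate values for dim spots and no normalization between arrays. Raw spot means and local background medians are deposited as intensity too. Per the file headers, the other columns are flags of 0 or 1 that mark spots as well above background, saturated or outliers. The deposited matrix of the series holds the same processed intensity multiplied by 1 factor per array (1, 2.10, 0.961 and 0.820), which gives all arrays a 75th percentile of 1078; this scaling is not stated in the sources used here and was read from the values.

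Spots of 1 probe were averaged after spots flagged as non-uniform or as population outliers on any array were left out, which removed 153 probes altogether. The plan had been to leave out every probe with a flagged spot; probes with other, unflagged spots stayed in, and the stricter reading was run as an alternative chosen after seeing the data. Main values are the log2 processed signal minus the log2 of the 75th percentile of each array over non-control spots. A probe was tested if well above background on at least 2 of 4 arrays, which left 27402 probes, and a gene name was represented by its tested probe with the highest mean, which left 18315 of 27745 names. Of the tested genes 12847 carried a RefSeq accession, 12159 matched the reference table, and 2450 names were updated from it. All 4 arrays were assigned to the groups by their titles.

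Lines and splenocytes were compared with limma 3.58.1 (lmFit and eBayes without trend, not robust) in R 4.3.3, with version 1.17.8 of the data.table package. P-values were adjusted by Benjamini-Hochberg and genes called at an adjusted p under 0.05. The test is two-sided. The prior had 2.31 degrees of freedom beside 2 residual ones and a prior SD of 0.185. The fold of a gene dim in a whole group and bright in the other is given as a lower bound, as is that of a named list member with 1 dim array, and log2 values of such genes rest on signals below background. The correlation of the deviations from the group mean between arrays of the same replicate number was 0.0135 across genes. This gave no sign that the numbers pair the samples, although it cannot exclude it. The numbers were taken not to pair them, and a block for them is an alternative only. No line has a replicate array, so lines were compared by size alone, with list medians set against 10000 random lists matched on mean expression. In simulated data of the same size with 200 genes changed, 0 of 67 genes changed 2-fold were called. Of those changed 4-fold, 42 of 67 (62.7%) were called, and of those changed 16-fold, 62 of 66 (93.9%). Of the 112 calls 8 were false. With so few changed genes the adjusted threshold is stricter than in the data, where 63.2% of genes were called. These shares therefore do not give the recall of the comparison itself. Where far more of the genes had been changed, 2.82% of 8262 calls were false. The simulated noise was independent between genes and drawn from limma's own prior, without shared array effects. These false shares therefore check the fit and not the calls made in the data.

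Gene lists, 30 in all with 557 entries, of which 491 were tested and 10 had no probe, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which gave 28 lists; the dopamine receptors (3 tested) and the sex check (1 tested) were too few. The lists were dopamine receptors, dopamine synthesis, neighbours of Drd3, cAMP and Gi signalling, mature B cell identity, follicular and marginal zone B cells with homing, pro-B and pre-B cells, germinal centre, plasma cell, MHC class II, MHC class I presentation, cell cycle, ribosome biogenesis, lymphoma oncogenes and tumour suppressors, p53 targets, the BCL2 family, NF-kappaB targets, immediate-early genes, the interferon response, glycolysis and hypoxia, cholesterol biosynthesis, the amino acid response, T cells, NK cells, macrophages with monocytes and neutrophils, dendritic cells, erythroid cells, megakaryocytes, stroma with endothelium, and a sex check. The p53 and BCL2 lists share 5 entries each with other lists, and the pro-B, oncogene, immediate-early and amino acid lists 1 each.

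Lists, tests, the main alternatives and the rule for named genes were fixed before the data were examined. The rule names all dopamine receptors; the 10 largest increases and 10 largest decreases among called genes well above background on all arrays with both lines on one side of both splenocyte samples; the 5 largest bounds in each direction among called genes bright in 1 group and dim in the other; of each list up to 2 called members with the largest increase and up to 2 with the largest decrease, or the brightest member where under 2 are called, with any member of a short list allowed; and between the lines the 5 largest differences in each direction among genes bright in both and the 5 largest bounds in each direction among genes bright in 1. Names that are not gene symbols and immunoglobulin or T cell receptor segments were passed over. Immunoglobulin probes were found by name, description and position, a choice made in part after seeing the data, and the bar of 4-fold for a probe that stays bright was also set then. Variable region probes are those of the kappa region and those of the heavy chain region beyond the last probe for the IgM constant region. For these probes a bound raises each line's signal to the lowest one well above background on its array.

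Alternatives were quantile normalization, centring on the median, a 75th percentile over probes bright on all arrays, normexp background correction with an offset of 50, the deposited matrix, no filter on dim probes, a filter for brightness on all 4 arrays, outlier flags kept, every probe tested separately, the mean over the probes of a gene, eBayes with a trend or robust, a replicate block, each array left out, other thresholds, camera with an estimated correlation, and fry. Where an array was left out, the lone sample of its group was assumed to vary like the other group. Precision rests on 2 arrays per group. The share of probes well above background was 66.6%, 60.8%, 63.5% and 63.1%, and 245 repeated probes had a spread of 0.0684, 0.0606, 0.0645 and 0.0633 (SD, log2) within splenocyte sample 1, splenocyte sample 2, line 1 and line 2. All arrays lie on 1 slide with 1 scan record, so slide and scan could not differ between groups.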

Results

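RNA abundance was measured on 4 single-colour mouse expression arrays, 2 with B220+ splenocytes of C57BL/6N mice and 2 with B-cell lymphoma lines, each line on 1 array. B220 is a surface marker used to select B cells from the spleen. Per the labels, the lines were established independently from mice carrying a dopamine receptor 3 transgene. Each array held 41174 different non-control probes. The number of probes well above background was 27418 in splenocyte sample 1, 25041 in splenocyte sample 2, 26160 in lymphoma line 1 and 25997 in lymphoma line 2. The 75th percentile of the processed signal was 1078, 514, 1122 and 1315 in the same order, and no spot was saturated. Across the 18315 genes tested, Pearson's r was 0.992 between the splenocyte samples, 0.991 between the lines and 0.834 to 0.846 between a splenocyte sample and a line. Genes are not independent replicates. The number of arrays, 2 per group, limits the precision of every value. The groups differ at once as lymphoma against normal cells, as cell lines against selected spleen cells, and in the mice of origin. No difference between them can be assigned to any of these alone.

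The first comparison asks how the lymphoma lines differ from normal B220+ splenocytes in the gene that the series concerns. Drd3, a Gi-coupled dopamine receptor, gave low signals in all samples. Its probe (mm8, chromosome 16, 43681810 to 43709955) gave a processed signal of 9.56 and 2.93 in the splenocyte samples and 14.1 and 14.9 in lines 1 and 2. These signals are not scaled between arrays, and the array of splenocyte sample 2 was dimmer as a whole. After scaling, on the log2 scale, the probe lay at −6.82 and −7.46 in the splenocyte samples and at −6.32 and −6.46 in the lines. It was well above background in both lines and in neither splenocyte sample. With the splenocytes at their bound the fold was 1.05, and the difference did not pass the threshold (0.75 ± 0.26 on the log2 scale, SE, n = 2 against 2; limma adjusted p = 0.0640), a value that rests on splenocyte signals not well above background. Drd5, a Gs-coupled dopamine receptor, was lower in the lines by at least 9.15-fold (log2 difference −4.98 ± 0.23, SE; adjusted p = 0.000329) at its brighter probe (chromosome 5, 38610288 to 38610347), while its other probe was well above background in 1 splenocyte sample and 1 line. Drd2 differed by −0.21 ± 0.17 (SE; adjusted p = 0.323), and by 0.32 after quantile normalization. Drd1 and Drd4 were too dim on every array to be tested.

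**Figure D1:**
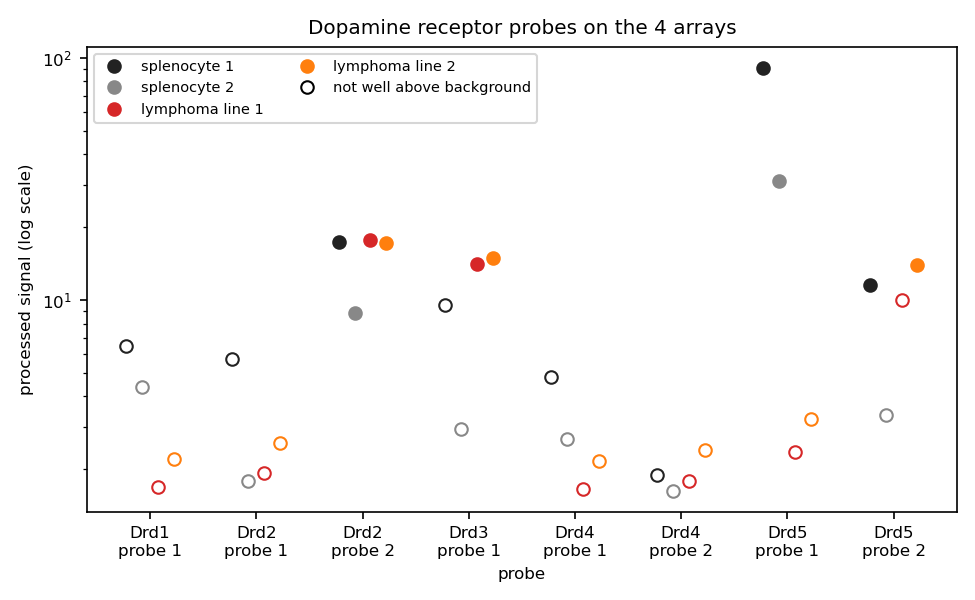
Processed signal (log scale, arbitrary units) of each dopamine receptor probe on each of the 4 arrays, not scaled between arrays. Open circles mark values not well above background. The Drd3 probe lay at 9.56 and 2.93 in the splenocyte samples and at 14.1 and 14.9 in the lines; the direction for Drd3 turned under normexp background correction and that for Drd2 under quantile normalization.

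The Drd3 value changed with the processing. It was 1.35 after quantile normalization (adjusted p = 0.0193), 0.87 after centring on the median (adjusted p = 0.0422), 1.07 without splenocyte replicate 1 (adjusted p = 0.0307) and −0.50 after normexp background correction (adjusted p = 0.212), and over all alternatives its adjusted p ran from 0.0193 to 0.216. Without splenocyte replicate 2 the difference was 0.43. With a replicate block the difference stayed at 0.75 and was called (limma adjusted p = 0.0488). The array carries 1 Drd3 probe, whose aligned span of 28146 bases is far longer than the 60 bases of the other receptor probes, and which therefore crosses an intron.

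Genes beside Drd3 on chromosome 16 went both ways. Of 10 tested neighbours, 3 rose, 5 fell and 2 did not pass (8 called when adjusted over the list alone). Naa50, an N-terminal acetyltransferase, rose 2.77-fold, and Boc, a Hedgehog co-receptor, rose at least 1.48-fold. Sidt1, a transmembrane protein linked to RNA transport, fell at least 86.6-fold, and Spice1, a centriole protein, fell 3.61-fold. The list as a whole was not called by camera (adjusted p = 0.773). The Boc call was lost without splenocyte replicate 2 (log2 difference 0.96, adjusted p = 0.118), without lymphoma replicate 1 (1.86, adjusted p = 0.0641), without lymphoma replicate 2 (1.15, adjusted p = 0.161), with a percentile over probes bright on all arrays (adjusted p = 0.0594), with no filter on dim probes (0.0858) and with a replicate block (0.0701), and under normexp its value was −0.30; over all its alternatives the adjusted p ran from 0.0213 to 0.403.

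Genes of dopamine handling and of receptor signalling also went both ways. Of 8 tested genes of dopamine synthesis, transport and breakdown, 2 rose, 1 fell and 5 did not pass (3 called when adjusted over the list alone; camera adjusted p = 0.840). Gch1, which makes the first step towards the tetrahydrobiopterin cofactor, rose 1.86-fold, and Maoa, a monoamine oxidase, fell at least 14.0-fold. The median of that list was 0.05, its mean −0.42, and camera's direction was up. Of 25 tested genes of cAMP and Gi signalling, 8 rose, 10 fell and 7 did not pass (18 called when adjusted over the list alone; camera adjusted p = 0.903). Adcy6, an adenylyl cyclase, rose 8.80-fold and Prkar2a, a regulatory subunit of protein kinase A, rose 8.50-fold, while Adcy3, another cyclase, fell at least 13.3-fold and Pde4d, a cAMP phosphodiesterase, fell at least 9.85-fold. The median of the signalling list was −0.18 and its mean −0.19, against camera's direction of up. The Gch1 call was lost with the mean over its probes (0.52 on the log2 scale, adjusted p = 0.0540) and without splenocyte replicate 1 (0.85, adjusted p = 0.0534), within a range of 0.00160 to 0.0540 over all its alternatives.

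The second part of the comparison covers all genes. Of the 18315 genes tested, 11581 (63.2%) were called at an adjusted p under 0.05 by limma, of which 5609 were higher and 5972 lower in the lines; 12391 had an unadjusted p under 0.05. At least a 2-fold change was seen in 3935 genes that rose and 4474 that fell, and at least a 16-fold change in 395 and 903. Well above background on both line arrays and on neither splenocyte array were 522 genes, and the reverse held for 958. In 15572 genes (85.0%) both lines lay on one side of both splenocyte samples, against 33.3% by chance. The p-values measure only the spread between these samples, which may be technical: the median within-group SD was 0.116 for the splenocytes and 0.161 for the lines, against 0.0606 to 0.0684 between repeated spots of one array. A scaling can move the balance: the median difference over all genes was −0.05, and quantile normalization moved it by 0.14, centring on the median by 0.12, a percentile over probes bright on all arrays by −0.13 and normexp by −0.26, so that 43.6% to 53.2% of called genes were higher, against 48.4%.

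Among genes well above background on all arrays, the largest increases were those of Cth, which cleaves cystathionine to cysteine (402-fold), Syngr1, a synaptic vesicle protein (294-fold), Cdkn2b, an inhibitor of CDK4 and CDK6 (232-fold), and Slc1a4, a neutral amino acid transporter (219-fold). The next were Sh3gl3 (178-fold), Nkpd1 (174-fold), Kndc1 (157-fold), Camk4 (147-fold), Cited1 (136-fold) and Cdkn2a (136-fold). Kndc1 ranged from 101-fold without splenocyte replicate 1 to 244-fold without splenocyte replicate 2. Of genes above background in the lines and in neither splenocyte sample, the largest bounds were for Pgbd5 (at least 1740-fold), Itga8 (at least 533-fold), Trp63, a p53 family member (at least 455-fold), Rcan2 (at least 384-fold) and Axin2, a Wnt target (at least 313-fold). Such a bound sets the mean of the bright group against the mean, over the dim arrays, of the larger of the lowest signal well above background on that array and the probe's own signal.

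The largest decreases included genes of the follicular and homing list and of the immediate-early list. Icosl, the ligand of the costimulatory receptor ICOS, fell 1548-fold, Fos, an immediate-early transcription factor, 1504-fold, Pla2g2d, a secreted phospholipase, 1412-fold and Adgre5, an adhesion receptor of leukocytes, 1384-fold. Evl fell 1035-fold, Rgs1 745-fold, Cr2, the complement receptor CD21, 735-fold, Rasgef1b 629-fold, Abca1, a cholesterol exporter, 608-fold and Rcor1 573-fold; Fos, Evl and Rcor1 lie on chromosome 12. Of genes above background in the splenocytes and in neither line, the largest bounds were for Klf4 (at least 7178-fold), Fcer2a, the low-affinity IgE receptor CD23 (at least 2149-fold), Cpm (at least 1728-fold), Hs3st1 (at least 1237-fold) and Lrrk2 (at least 1216-fold). All of these genes were called, and their calls held without any one array. The array reports 6229 genes by several probes, and in 541 of these called probes went opposite ways.

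Of 28 gene lists with enough tested members, camera called 11, with 4 higher and 7 lower in the lines. None of these 11 calls held with an estimated correlation between genes, where camera called 0 of 28 lists. That form rests on the 2 residual degrees of freedom, so it has little power here. For the immediate-early, amino acid and follicular lists the estimated correlation was −0.022, −0.015 and −0.0084, below the preset 0.01. A higher correlation thus did not cost these lists their calls. For the other called lists it was above 0.01, up to 0.96 for cholesterol biosynthesis. Fry, which tests whether the genes of a list move one way on balance, called 16 lists, 3 higher and 13 lower. It found change in either direction in all 28. With 63.2% of all tested genes called, nearly any list would show such change, so this result sets no list apart.

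Genes of cell division, ribosome production, cholesterol synthesis and the amino acid response were higher in both lines. Of 40 cell cycle genes 38 rose, none fell and 2 did not pass (39 called when adjusted over the list alone), with a median log2 difference of 2.26. Examples are Bub1b, a spindle checkpoint kinase (14.0-fold), and Ttk, which recruits checkpoint proteins to kinetochores (13.1-fold). Camera gave the list an adjusted p of 6.73e-10, and the adjusted p = 0.759 with an estimated correlation. Of 24 genes of ribosome biogenesis 19 rose, none fell and 5 did not pass (21 called when adjusted over the list alone; median 1.17), among them Polr1b, a subunit of RNA polymerase I (4.65-fold), and Nolc1, a nucleolar chaperone (3.80-fold). Camera gave an adjusted p of 0.000256, and the adjusted p = 0.796 with an estimated correlation.

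Of 23 cholesterol biosynthesis genes 16 rose, 1 fell and 6 did not pass (19 called when adjusted over the list alone; median 2.13). Sqle, squalene epoxidase, rose 10.01-fold and Cyp51, lanosterol demethylase, 7.04-fold. Pmvk, phosphomevalonate kinase, fell 1.51-fold, a call lost without splenocyte replicate 1 (adjusted p = 0.143), splenocyte replicate 2 (adjusted p = 0.134) or lymphoma replicate 2 (adjusted p = 0.0807), when centred on the median (0.0804), with no filter on dim probes (0.0922) and with a replicate block (0.0572), where over all its alternatives the adjusted p ran from 0.0103 to 0.143. The camera adjusted p was 0.000330, and the adjusted p = 0.796 with an estimated correlation. Of 19 genes of the amino acid response and serine synthesis 15 rose, 1 fell and 3 did not pass (16 called when adjusted over the list alone; median 2.84). Chac1, a glutathione-degrading enzyme, rose 65.7-fold (41.2 to 105 when an array was left out, the lowest without splenocyte replicate 1 and the highest without splenocyte replicate 2) and Pycr1, a proline synthesis enzyme, 53.8-fold (34.4 to 84.1, the same arrays), while Vldlr, a lipoprotein receptor, fell at least 3.70-fold. For the amino acid list, camera gave an adjusted p of 1.12e-05, and the adjusted p = 0.458 with an estimated correlation.

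**Figure D2:**
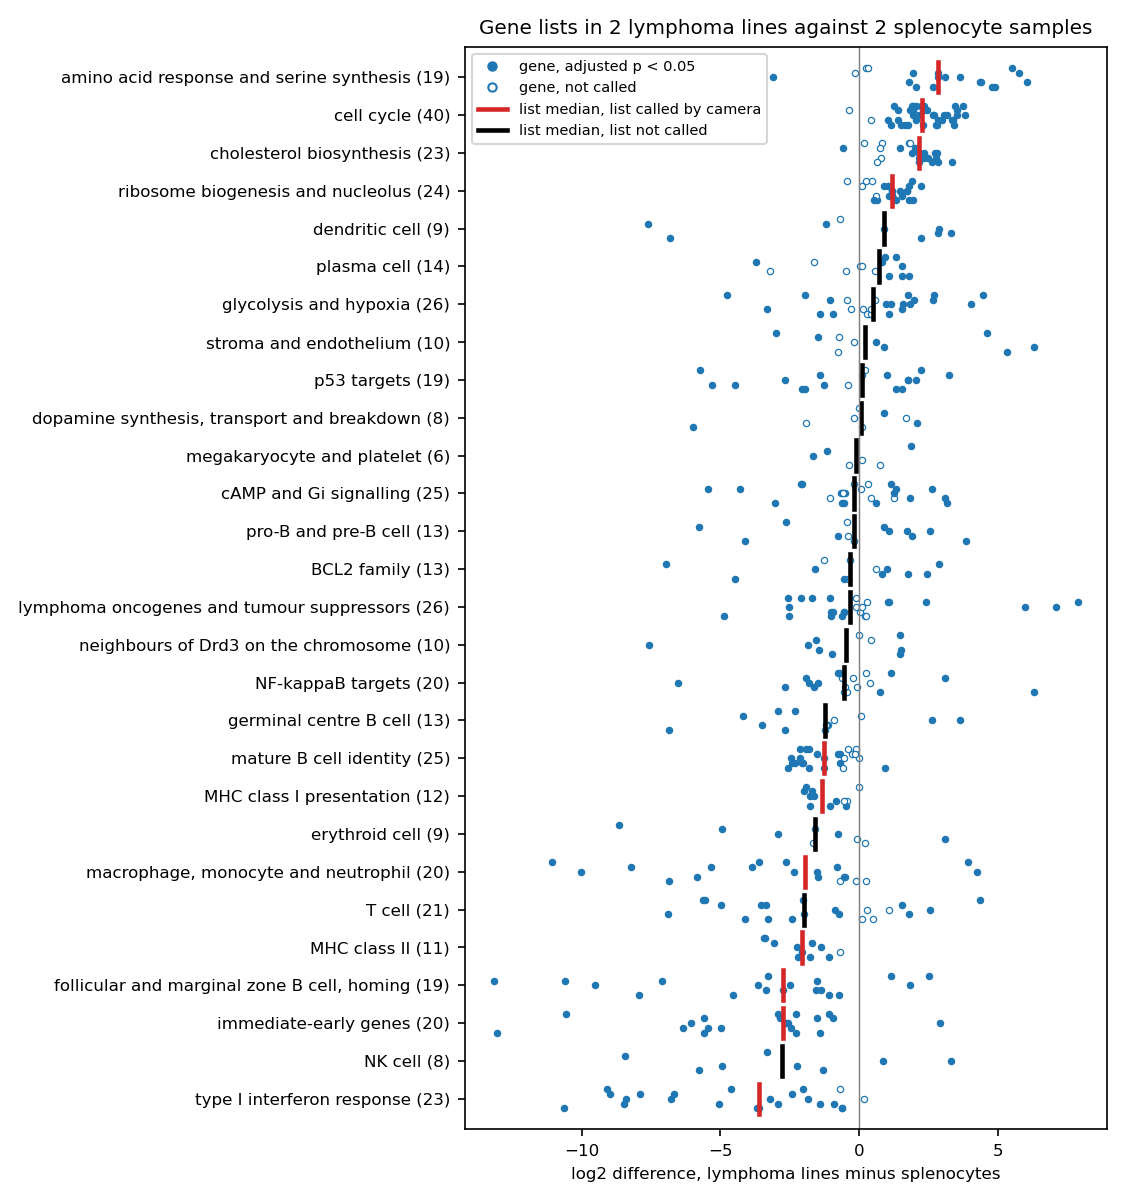
Log2 difference of the lymphoma lines from the splenocytes for each tested gene (points, filled where the adjusted p is under 0.05) of the 28 tested lists, with the list median as a bar and the number of tested genes in brackets. Medians run from −3.60 for the interferon response to 2.84 for the amino acid response; bars are red for the 11 lists called by camera, none of which was called with an estimated correlation.

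Genes of mature B cells, and those of follicular and marginal zone cells, were lower in the lines. Of 25 genes of mature B cell identity 1 rose, 17 fell and 7 did not pass (19 called when adjusted over the list alone; median −1.29). Spib, an Ets factor of B cells, rose 1.91-fold, while Cd180, a Toll-like receptor homologue, fell 6.00-fold and Fcrla, an Fc receptor-like protein, fell 5.54-fold. All 25 were well above background in both lines. The camera adjusted p was 0.000555, and the adjusted p = 0.759 with an estimated correlation. Of 19 genes of follicular and marginal zone B cells and homing 3 rose and 16 fell (19 called when adjusted over the list alone; median −2.74). Plscr1, a phospholipid scramblase, rose 5.65-fold and Cd9, a tetraspanin, 3.57-fold; Fcer2a fell at least 2149-fold and Icosl 1548-fold. For the follicular list, camera gave an adjusted p of 0.000296, and the adjusted p = 0.458 with an estimated correlation.

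Antigen presentation genes were lower too. Of 11 MHC class II genes 10 fell and none rose (11 called when adjusted over the list alone; median −2.06). H2-Ob and H2-Oa, which form the peptide-loading regulator H2-O, fell 10.8-fold and 10.7-fold, and Cd74, the invariant chain, was the member not called (−0.69, adjusted p = 0.0554). The camera adjusted p was 0.000330, and the adjusted p = 0.749 with an estimated correlation. Of 12 genes of MHC class I presentation 9 fell, none rose and 3 did not pass (9 called when adjusted over the list alone; median −1.35). H2-T23 fell 3.96-fold and H2-Q7 3.80-fold, both non-classical class I chains. For class I, camera gave an adjusted p of 0.00503, and the adjusted p = 0.759 with an estimated correlation.

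Immediate-early and interferon-response genes were lower in the lines. Of 20 immediate-early genes 1 rose and 19 fell (20 called when adjusted over the list alone; median −2.76). Ier3 rose 7.49-fold, while Klf4, a zinc finger factor, fell at least 7178-fold and Fos 1504-fold. The camera adjusted p was 3.58e-06, and the adjusted p = 0.458 with an estimated correlation. Of 23 type I interferon response genes 21 fell, none rose and 2 did not pass (22 called when adjusted over the list alone). Their median was −3.60, or −3.22 with dim genes set at their bound. Rtp4, a chaperone of receptors, fell at least 1002-fold and Oas2, a sensor of double-stranded RNA, at least 164-fold. For the interferon list, camera gave an adjusted p of 3.51e-07, and the adjusted p = 0.734 with an estimated correlation.

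Beside these groups come the lists of other cell types of the spleen, set as a check on the B220+ selection and on the lines. Which cells gave their signals was not tested, so a lower value need not be a change within B cells. The list of macrophage, monocyte and neutrophil genes was called lower in the lines, and no other of these lists was called by camera. Of its 20 genes 2 rose, 14 fell and 4 did not pass (18 called when adjusted over the list alone; median −1.94, or −1.67 at the bounds). Lyz1 and Lyz2, the lysozymes, which share 1 probe, fell at least 469-fold, and S100a9, a neutrophil calcium-binding protein, fell at least 753-fold and was well above background in 1 of 2 lines. Adgre1, the macrophage antigen F4/80, rose 18.7-fold and Hmox1, heme oxygenase, 14.9-fold. The camera adjusted p was 0.00447, and the adjusted p = 0.693 with an estimated correlation. The list lost its call among genes well above background on all arrays (adjusted p = 0.269; over all its alternatives 0.000584 to 0.693).

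Of 21 T cell genes 4 rose, 13 fell and 4 did not pass (17 called when adjusted over the list alone; median −1.99; camera adjusted p = 0.146). Thy1 fell at least 86.7-fold and Ccl5, a chemokine, 49.0-fold, while Cd3g, a chain of the T cell receptor complex, rose 20.5-fold and Cd5, a receptor that B-1 cells also carry, 5.89-fold. The T cell list was called with the mean over each gene's probes (adjusted p = 0.0389; over all its alternatives 0.0140 to 0.796). Of 8 NK cell genes 2 rose and 6 fell (8 called when adjusted over the list alone; median −2.78, or −1.93 at the bounds; camera adjusted p = 0.145). Klrd1 fell at least 76.0-fold and Gzma, a granzyme, at least 18.7-fold, while Klrg1 rose 9.83-fold and Prf1, perforin, 1.80-fold. The Prf1 call was lost without splenocyte replicate 1 (adjusted p = 0.103), splenocyte replicate 2 (adjusted p = 0.0658) or lymphoma replicate 1 (adjusted p = 0.0539), under normexp (0.0542) and with no filter on dim probes (0.0571), where over all its alternatives the adjusted p ran from 0.0117 to 0.103.

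Lists of remaining cell types were small and mixed. Of 9 dendritic cell genes 5 rose, 3 fell and 1 did not pass (9 called when adjusted over the list alone; camera adjusted p = 0.840). The median of 0.89 and camera's direction were up and the mean was −0.47. Batf3, a transcription factor, rose 9.93-fold (6.53 without lymphoma replicate 1, 15.1 without lymphoma replicate 2) and Zbtb46 7.36-fold, while Itgax, the integrin CD11c, fell at least 122-fold and Clec10a, a lectin, at least 24.9-fold. Of 9 erythroid genes 1 rose, 5 fell and 3 did not pass (7 called when adjusted over the list alone; median −1.58; camera adjusted p = 0.146): Tfrc, the transferrin receptor of dividing cells, rose 8.45-fold, Car2, carbonic anhydrase, fell at least 133-fold and Alas2, the erythroid heme synthesis enzyme, at least 7.78-fold.

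Of 6 megakaryocyte genes 1 rose, 2 fell and 3 did not pass (3 called when adjusted over the list alone; median −0.13; camera adjusted p = 0.855). Gp6 rose at least 2.83-fold, with a value of −0.09 under normexp, while Treml1 fell at least 3.04-fold. Of 10 genes of stroma and endothelium 5 rose, 2 fell and 3 did not pass (7 called when adjusted over the list alone; median 0.20; camera adjusted p = 0.557). Pdgfrb, a growth factor receptor, rose at least 41.9-fold and Madcam1, an addressin, 39.5-fold, while Pecam1, an adhesion molecule of endothelium and leukocytes, fell 8.02-fold and Kdr at least 2.03-fold (−0.73 and not called under normexp). Xist, the X inactivation transcript, was well above background on all 4 arrays and fell 1.70-fold (adjusted p = 0.0101; 0.0559 without splenocyte replicate 1 and 0.0718 without splenocyte replicate 2, the highest of the leave-one-out values, whose lowest was 0.0247). Called Xist probes went opposite ways, and the mean over its probes differed by −0.09 (adjusted p = 0.685). The Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were too dim to test, and the labels give all samples as female.

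Genes of other B cell stages were mixed. Of 13 germinal centre genes 2 rose, 8 fell and 3 did not pass (10 called when adjusted over the list alone; median −1.22; camera adjusted p = 0.0932, and 0.0210 without splenocyte replicate 2, from 0.0210 to 0.796 over all its alternatives). Mef2b, a transcription factor of germinal centre cells, rose 12.4-fold and Plxnb2, a plexin, 6.06-fold. Bcl6, the repressor that germinal centre cells depend on, fell 116-fold and Basp1 at least 15.6-fold, the latter well above background in 1 of 2 lines. Of 14 plasma cell genes 7 rose, 1 fell and 6 did not pass (8 called when adjusted over the list alone; median 0.70; camera adjusted p = 0.315). Prdm1, which drives plasma cell differentiation, rose 3.47-fold and Ell2, an elongation factor, 2.89-fold, while Tnfrsf17, the receptor BCMA, fell 13.2-fold. The Ell2 call was lost with the mean over its probes (adjusted p = 0.0520). Of 13 genes of pro-B and pre-B cells 6 rose, 4 fell and 3 did not pass (10 called when adjusted over the list alone; camera adjusted p = 0.892). The median and mean of that list were both −0.19 against camera's direction of up. Myb, a transcription factor of progenitors, rose 14.4-fold and Arpp21 at least 1.32-fold (−0.19 on the log2 scale under normexp, and not called with no filter on dim probes), while Cd93 fell 55.3-fold, with leave-one-out values of 26.7 without lymphoma replicate 1 to 115 without lymphoma replicate 2, and Sox4 at least 10.4-fold.

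Lymphoma genes, p53 targets and survival genes moved in both directions. Of 26 lymphoma oncogenes and tumour suppressors 6 rose, 12 fell and 8 did not pass (18 called when adjusted over the list alone; camera adjusted p = 0.644, direction down). The median was −0.33 and the mean 0.15. Cdkn2b and Cdkn2a, the neighbouring genes of cell cycle inhibitors, rose 232-fold and 136-fold, while Hoxa7, a homeobox gene, fell at least 29.5-fold, well above background in 1 of 2 lines, and Hhex, another homeobox gene, 5.86-fold. Myc, a driver of growth singled out here after its value was seen, fell 5.75-fold (log2 difference −2.52, adjusted p = 0.00222). Of 19 p53 targets 8 rose, 8 fell and 3 did not pass (17 called when adjusted over the list alone; camera adjusted p = 0.892, direction up; median 0.11, mean −0.54). Tnfrsf10b, a death receptor, rose 9.46-fold and Zmat3 4.65-fold, while Plk2, a kinase, fell 53.3-fold and Phlda3, an inhibitor of AKT, at least 18.2-fold.

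Of 13 BCL2 family genes 5 rose, 4 fell and 4 did not pass (12 called when adjusted over the list alone; camera adjusted p = 0.978, direction up). The median was −0.33 and the mean −0.47. Bcl2l1, the survival protein BCL-XL, rose 7.28-fold and Bcl2l11, the death protein BIM, 5.36-fold, while Bcl2l2, a survival protein, fell at least 97.7-fold and Pmaip1, the death protein NOXA, 22.2-fold. Of 20 NF-kappaB targets 4 rose, 8 fell and 8 did not pass (12 called when adjusted over the list alone; median −0.54; camera adjusted p = 0.315). Ccl22, a chemokine, rose at least 28.1-fold and Cd44, a hyaluronan receptor, 8.37-fold, while Lta, lymphotoxin, fell 91.7-fold and Irf1 6.46-fold. Of 26 genes of glycolysis and hypoxia 12 rose, 6 fell and 8 did not pass (20 called when adjusted over the list alone; median 0.49; camera adjusted p = 0.146). Vegfa, a vascular growth factor, rose 22.1-fold and Egln3, a prolyl hydroxylase, 16.1-fold, while Aldoc, an aldolase, fell 27.1-fold and Bnip3, a mitophagy receptor, 9.94-fold. The glycolysis list was called under normexp (adjusted p = 0.0268), with no filter on dim probes (0.0170) and without lymphoma replicate 2 (0.0432), within a range of 0.0170 to 0.875 over all its alternatives.

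Immunoglobulin probes fell together, apart from a small set. Of 126 probes in the immunoglobulin regions that were well above background in both splenocyte samples, 105 were lower in the lines, 16 higher and 5 not called (limma on probes), with a median log2 difference of −7.22, or −6.30 at the bounds. The medians were −8.91 for 68 heavy chain probes (−7.43 at the bounds) and −6.16 for 48 kappa probes (−6.11 at the bounds). Of 10 lambda probes 9 rose, 8 of them for Igl-V1 and 1 for Igll1, a surrogate light chain gene that is also in the pro-B list, while the IGLC3 probe fell, so that this count rests on few transcripts. Of 99 probes in heavy and kappa variable regions, 92 were lower and 7 higher, and 79 were at least 16-fold lower in each line at the bounds. Probes that stayed within 4-fold of the splenocyte mean, or above it, numbered 8 in line 1 and 9 in line 2, of which 8 were shared. Among them, probes for the variable segments IGHV5-17, IGHV5S24 and IGKV8-16 rose by 3.56, 3.66 and 4.13 on the log2 scale, and one for Igk-V38 by 2.14. A pair of probes for Igh-6, the constant region of IgM, differed by −0.60 and 0.42 and were not called, while a probe for IGHG2C, a constant region of IgG, differed by −9.88 and one for IGHD, that of IgD, by −5.70, both well above background on all arrays. The segments were chosen after their values were seen, probes of related segments can bind the same transcripts, and under normexp 12 variable probes stayed bright in both lines.

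**Figure D3:**
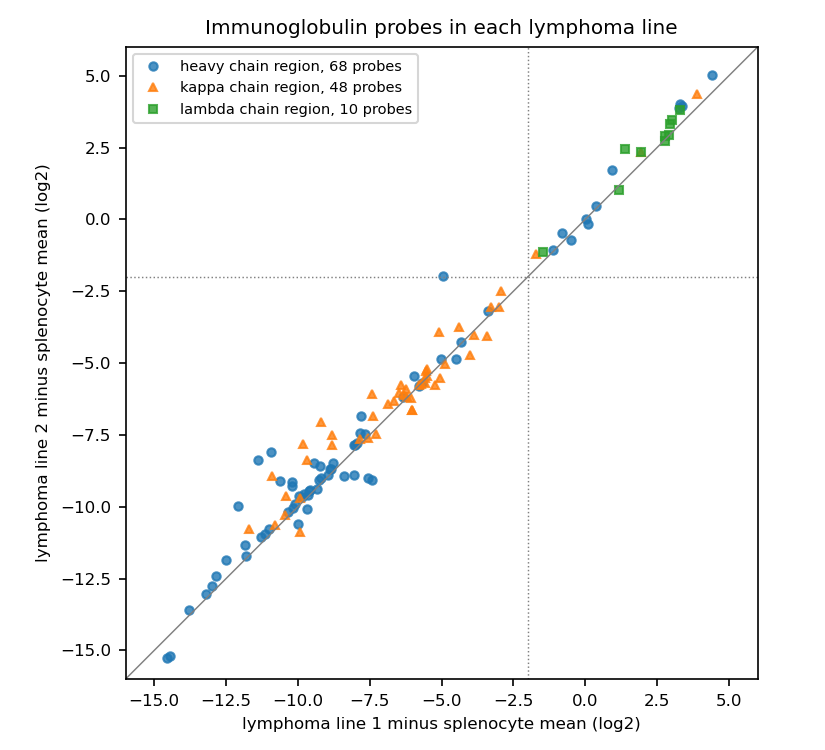
Log2 difference from the splenocyte mean for each of the 126 immunoglobulin probes, line 1 on the horizontal and line 2 on the vertical axis, with heavy, kappa and lambda chain regions marked apart; the diagonal marks equal values and the dotted lines a value −2 from the mean, that is 4-fold lower. In each line most heavy and kappa probes lie far below 0, while 24 probes lie above both dotted lines, with 1 more above that of line 2 alone.

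The second comparison sets the lymphoma lines against each other. Each line has 1 array, so no test was made and sizes only are given, beside the same measure between the splenocyte samples. Of 16707 genes well above background on both line arrays, 713 (4.27%) differed at least 2-fold, 129 higher in line 1 and 584 higher in line 2, and 33 differed at least 4-fold. Between the splenocyte samples, 322 of 16568 genes (1.94%) differed at least 2-fold and 39 at least 4-fold. Under normexp the counts at 2-fold were 153 between the lines and 181 between the splenocyte samples, so their order turned. Genes of cholesterol biosynthesis were higher in line 1 in 23 of 23 cases, with a median of 1.08 against −0.20 to 0.27 for 10000 random lists matched on expression and a median of 0.22 between the splenocyte samples. Plasma cell genes were lower in line 1 in all 14 cases, with a median of −0.60 against −0.36 to 0.33, and −0.32 between the splenocyte samples. Ribosome biogenesis genes had a median of 0.45 (24 of 24 higher in line 1; 0.07 between the splenocyte samples) and glycolysis genes one of 0.34 (22 of 26; 0.00 between the splenocyte samples). Cell cycle genes had a median of 0.31 (39 of 40), less than the 0.44 between the splenocyte samples.

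Single genes also set the lines apart. Higher in line 1 were Sgsm1 (12.5-fold), Pkd1l2 (11.4-fold), Mras, a Ras-related GTPase (7.29-fold), Myh4, a muscle myosin (4.25-fold), and Rhox5, a homeobox gene (3.98-fold). Higher in line 2 were Cryab, a small heat shock protein (11.0-fold), Ang4 (10.9-fold), Jchain, the joining chain of polymeric immunoglobulin (8.56-fold), Kcnmb4 (6.69-fold) and Impg1 (5.62-fold). Well above background in line 1 only were Fbxl21 (at least 13.3-fold higher), Pltp (3.12), Hs3st2 (3.10), Cacna2d1 (2.75) and Olfr476 (2.41). Well above background in line 2 only were Armcx2 (at least 25.3-fold higher), Dnah2 (18.9), Hsd17b11 (8.99), Nanog (8.62) and Nanos2 (7.33). All 20 kept their direction under the 5 other scalings.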

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

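No test was run on these values. For 6 genes, each named for its large difference between the lines, one line lay above both splenocyte samples and the other below both, among 142 named genes and 28 lists looked at in this way. Each line has 1 array, so the difference was not tested. Values are log2 differences of line 1 from line 2. Higher in line 1 were Fbxl21 (5.70; 1.67 in line 1 and −4.03 in line 2 against the splenocyte mean), Hs3st2 (3.39) and Olfr476 (2.22). Higher in line 2 were Ang4 (−3.44), Nanog (−5.28) and Nanos2 (−4.98). Ang4 was well above background in both lines; the lower line of the 5 others was not, so their differences are set against values below background. With that line at its bound the differences are at least 13.3-fold for Fbxl21, 3.10-fold for Hs3st2, 2.41-fold for Olfr476, 8.62-fold for Nanog and 7.33-fold for Nanos2. For Hs3st2, Olfr476 and Nanog, 1 splenocyte sample was not well above background either, and the order of that sample and the lower line carries no information. Over all tested genes 685 (3.74%) showed such opposite sides, against 16.7% by chance, and no list did.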

How the results depend on the processing

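Leaving out probes with any flagged spot, and the other scalings of the immunoglobulin probes, were chosen after seeing the data; the other alternatives were planned. The count of genes called, 11581, stayed between 7947 and 12027 under 19 alternatives; it was 17756 of 27402 when every probe was tested, since more features were tested, and 5082 when limma's treat asked for a change beyond 2-fold. With quantile normalization 10803 of the main calls kept their direction and call, with normexp 9610 and with the stricter flag rule, which leaves 40 fewer genes, 11557. Without an array the count ran from 8412 to 11000. A replicate block gave 10804, although the numbers gave no sign of pairing the samples.

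Of 122 named genes, 116 to 122 kept direction and call under each alternative (119 of 119 under the stricter flag rule, 83 of 83 among genes bright on all 4 arrays, where Drd3 has no value). The reversals were Drd2 at 0.32 with quantile normalization, and Boc at −0.30, Arpp21 at −0.19 and Gp6 at −0.090 under normexp, all dim in 1 group or near background. Drd3 was 1.35 with quantile normalization, 0.87 when centred on the median, 0.75 with a replicate block (adjusted p = 0.0488, in a range of 0.0193 to 0.216), −0.50 under normexp and 0.43 to 1.07 without an array. The cause was not tested for any of these.

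Camera with an estimated correlation called 0 of 28 lists, against 11 with the preset correlation and 16 by fry. It rests on the 2 residual degrees of freedom, so a lost call need not come from correlation between genes. Its adjusted p was 0.759 for cell cycle, mature B cell identity and MHC class I, 0.796 for ribosome biogenesis and cholesterol, 0.458 for the amino acid response, follicular and homing genes and immediate-early genes, 0.749 for MHC class II, 0.734 for the interferon response and 0.693 for macrophages. Fry asks another question: it called neighbours of Drd3 (0.0382), germinal centre (0.0273), T cell (0.0140), NK cell (0.00531), erythroid (0.00531) and stroma (0.0186) genes, did not call ribosome (0.0641) and cholesterol (0.0768) genes, and turned the direction of dopamine synthesis (0.0673), oncogenes (0.0501), BCL2 family (0.0209) and dendritic cell (0.177) genes. Glycolysis was called under normexp (0.0268) and with no filter (0.0170), with 0.0432 to 0.203 without an array; T cell genes were called with the mean of probes (0.0389), macrophage genes were not called among genes bright on all arrays (0.269), and germinal centre genes ran from 0.0210 to 0.118 without an array. Uncalled lists whose direction turned were cAMP signalling (0.944 with quantile normalization, 0.897 with the mean of probes, 0.827 to 0.958 without an array), pro-B (0.683 to 0.990 without an array), p53 targets (0.965 with quantile normalization, 0.855 under the stricter flag rule, 0.889 to 0.976 without an array), megakaryocyte (0.992 with quantile normalization) and BCL2 (0.827 with quantile normalization, 0.977 when centred on the median, 0.993 with flags kept, 0.963 with every probe, 0.997 with a replicate block, 0.815 under the stricter flag rule, 0.889 to 0.961 without an array). The cause was not tested.

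Between the lines 553 to 764 genes differed 2-fold under 8 alternatives, against 713, and 153 under normexp, which adds an offset to all signals; the medians of cholesterol, plasma cell, ribosome, cell cycle and glycolysis genes kept their sign. The number of immunoglobulin probes lower in the lines was 104 or 105 under the other scalings, and 8 to 12 variable probes stayed bright in both. Blocks for slide or scan were not run, as there was 1 of each, and camera has no robust form. Signal over background limits Drd3 and every gene given as a bound.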

Other observations

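The tests in this part were chosen after the result was seen, except that the Drd3 fit under normexp and the difference of cholesterol genes between the lines were planned, and only their use against an explanation was chosen later. Genes of chromosome 12 were lower in both lines as a group. Among 15082 genes well above background on all 4 arrays and placed on 20 chromosomes (mm8), the 546 of chromosome 12 had a median log2 difference of −0.63, below the range of −0.25 to 0.24 for random sets matched on expression. Of these, 283 (51.8%) were called lower and 86 higher, and the medians were −0.59 in line 1 and −0.64 in line 2. On the other chromosomes the share called lower ran from 24.4% (chromosome 5) to 39.6% (chromosome 4). Camera gave an adjusted p of 0.000223, and the adjusted p = 0.337 with an estimated correlation. As for the gene lists, that form rests on few degrees of freedom and has little power. The difference of chromosome 12 from the other chromosomes ran from −0.43 to −0.73 over the alternatives run for it. These were the other scalings, the filter for brightness on all 4 arrays, and each array left out. Fos, Evl and Rcor1, which had fallen 1504-fold, 1035-fold and 573-fold, lie on it and are among these genes, so they add no separate support. Next came chromosome 4 with a median of −0.24 and chromosome 5 with 0.22, each beyond its random sets but not called by camera (adjusted p = 0.566 for each), and no other chromosome passed the range of its random sets.

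The lower signal along chromosome 12 is set against technical and other explanations. Immunoglobulin genes do not account for it, since without the heavy chain region the median of 521 genes was −0.59, still outside its random range. Random sets matched on signal level did not reach the median, whose percentile among them was 0. This is the same result that singled the chromosome out, so it is no separate test of a dependence on signal level. Fewer copies of the chromosome in both lines stays open and may explain it: 10 of 11 windows of 10 Mb lay below the all-gene median in both lines, although the windows had been looked at beforehand. RNA does not measure copy number, and DNA of the lines would be the test.

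The same few immunoglobulin probes stayed bright in both lines, 8 in the heavy and kappa variable regions. Hybridisation of the same RNA to both line arrays is argued against, since cholesterol genes differed by 1.08 between them, beyond matched random lists. Descent of both lines from cells with the same rearrangements stays open. Only 1 variable probe stayed within 4-fold of the splenocyte mean in 1 line and not in the other. That probe, for Ighv1-66, was called lower (limma adjusted p = 0.0402) and lay at −1.97 (log2) in line 2, just inside the bar. With a percentile over probes bright on all arrays, 8 probes stayed bright in each line, so this difference rests on the bar. Probes of related segments can bind the same transcript, so the shared number does not measure chance. The labels give the lines as established independently. If they shared descent, the comparison with the splenocytes would not rest on independent lymphomas. Its p-values would then not describe lymphomas in general. Probes that bind other segments of the same family stay open, since 8 probes exceed the pair of segments that a single clone rearranges, and sequencing the rearrangements would decide.

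The Drd3 probe was near background in both groups. Swapped labels would leave both groups near background, so they could not explain this. A swap is also argued against on other grounds. With dim signals at their bound, 79 of 99 heavy and kappa variable probes were at least 16-fold lower in both arrays labelled lymphoma. At least 16-fold higher in both were 0, and the filter left out no such probe. These probes have no bearing on the Drd3 level. The background correction may set the direction of the difference, which was −0.50 under normexp. Transcripts that miss the exons of the probe stay open, since the array has 1 Drd3 probe. Quantitative PCR over several exons, with the transgene's own sequence, would test both the direction of the difference and such transcripts.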
